A study of Homo sapiens with 7 samples.

How the data were processed

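RNA of PANC1 cells was measured on 7 biotin-labelled Affymetrix arrays in 4 groups: siControl (n = 2), sip53 (n = 2), siControl with TNF (n = 1) and sip53 with TNF (n = 2). Groups, the TNF dose and the time were taken from the labels, which number the arrays 154 to 159 and 161. Replicate 1 of each group is an array from 154 to 157 and replicate 2 an array from 158 to 161. Array 160 was not analysed here.

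The deposited log2 expression values were made by the authors with RMA, which corrects background, normalizes arrays and summarises probes per transcript cluster. RMA and Partek are named in the submitters' processing notes, and their versions are not given in the sources used here. Per the labels, the arrays were Human Exon 1.0 ST, whereas the deposited identifiers (7892501 to 8180179) follow the numbering of Human Gene 1.0 ST transcript clusters, and the sources used here do not settle which is meant. Both deposited tables hold the same log2 values, with a largest difference of 0. The authors' deposited table also gives p-values and q-values, linear ratios and signed fold changes of sip53 against siControl, from an analysis of variance with terms for the siRNA, for TNF and for their product, per the file headers. These columns were used only for comparison.

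Of 32968 clusters, 2904 negative and 1195 positive control clusters were left out, and 28869 were tested with no filter on level, since the signals of the negative controls spread too widely to set a detection limit. A gene symbol was available for 22116 tested clusters (20102 distinct symbols) and not for 6753. Symbols were updated through a RefSeq accession in 19650 cases and a synonym in 716, were already current in 992, and were kept as in the file in 758. Of 38 names altered to dates, 2 could not be restored and were left unnamed. A gene with several clusters was represented in lists by the cluster with the highest mean over all arrays.

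Log2 values were fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups over all 7 arrays, moderated variances and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. The lone siControl array with TNF was thereby taken to vary like the others. The 5 comparisons were sip53 against siControl without TNF, TNF in siControl cells, TNF in sip53 cells, sip53 against siControl with TNF, and the difference of both TNF responses. The labels name no separate cultures, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value.

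Array numbers form 2 runs, 154 to 157 (run 1) and 158 to 161 (run 2), whose mean difference within groups was 0 in every cluster (largest run coefficient 6.7e-05 on the log2 scale). A difference between the runs was therefore removed from the values before deposit, although no label or header records that step. The authors' deposited p-values lay within 1% of those from an analysis of variance with a run term in 99.99% of clusters, against 3.37% without it. Deviations of arrays of the same run from their group means correlated at -0.353, -0.679 and -0.447, as the removal itself forces. The planned fit without a run term counts 3 residual degrees of freedom where 2 remain, so its p-values are too small. It was kept as planned, and values from a fit with the run as a block are given beside the results. Fold changes are the same in both fits, and differences within a run are not touched by the removal.

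Both fits were tested on simulated values of 28869 clusters with a run difference removed in the same way and 200 clusters changed. For the knockdown without TNF, the planned fit recovered 50.6%, 70.7% and 96.7% of changes of 0.5, 1 and 2 on the log2 scale with 89 false calls, and 12.6% of unchanged clusters had an unadjusted p under 0.05. With the run term the recovery was 1.23%, 27.6% and 75.4% with 2 false calls and a share of 5.69%. For the knockdown with TNF, 62.5% of all changes were recovered with 86 false calls without the run term, and 18.0% with 0 false calls with it. Of 80 simulated lists of 30 genes shifted by 0.3 for the knockdown without TNF, 80 were called, as were 2 of 320 lists not shifted. The simulated clusters varied independently of each other. These shares therefore do not show how often real lists, whose genes may vary together, are called wrongly.

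Gene lists were tested with camera (limma), which compares a list with all other genes, at a preset inter-gene correlation of 0.01, and again with a correlation estimated for each list. The estimate rests on the 3 residual degrees of freedom that the fit counts. It led to 0 calls in all 5 comparisons and was not tried on the simulated lists. How often it would find a shifted list is therefore unknown, and a miss there does not show that a list stayed unchanged. The same lists were tested with fry, which asks whether a list's genes move, on balance, one way, and does not compare them with other genes. The 20 lists tested held NF-kB target genes, feedback inhibitors of NF-kB, cytokines and chemokines, interferon-stimulated genes, MHC class I antigen presentation, target genes of wild-type p53, cholesterol synthesis, DNA replication, mitosis, epithelial junctions, mesenchymal genes, extracellular proteases and their inhibitors, TNF receptor signalling and apoptosis, the unfolded protein and amino acid stress response, hypoxia and glycolysis, immediate early genes, ribosomal proteins, and markers of leukocytes, of stromal and endothelial cells, and of pancreatic acinar and endocrine cells. In 11 of the 100 list results the median, the mean and the test differed in sign, and 0 of these were called. They were mesenchymal genes for the knockdown without TNF, p53 target genes for TNF in siControl cells, leukocyte markers and DNA replication genes for TNF in sip53 cells, hypoxia genes for the knockdown with TNF, cytokines and pancreatic markers for the difference of TNF responses, and stromal markers in every comparison except the knockdown without TNF.

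Lists, comparisons, tests and the rule for naming genes were fixed before the data were examined. CDKN1A, MDM2, NFKBIA, TNFAIP3, CXCL8, IL6, ICAM1 and MMP9 were named in every comparison. Further names were the genes past the threshold with the largest changes, or, where fewer than 3 passed in a direction, the 5 with the largest moderated statistic in that direction, and up to 3 members of each list with the smallest p. Some genes that this rule names are not reported here. Alternatives chosen beforehand were quantile normalization, median centring, leaving out the 25% dimmest clusters, trended and robust variances, array weights, only the groups compared, additive siRNA and TNF terms, the run as a block, an analysis of variance without moderation, other thresholds, all clusters of a gene, and leaving out each array of a group of 2. An analysis of variance with the run term, an additive model with the run term, and values within each run were added after the data had been seen. Plots were drawn with Python and matplotlib.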

Results

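PANC1, an established human pancreatic cancer cell line that carries a mutant p53, was studied with a control siRNA (siControl) or an siRNA against p53 (sip53). Cells of each kind were left without TNF or received 0.5 ng/ml of TNF alpha, an inflammatory cytokine that activates NF-kB, and were harvested after 24 h. RNA was measured on 7 arrays, 2 each for siControl, sip53 and sip53 with TNF, and 1 for siControl with TNF. The array numbers form 2 runs, the first with 1 array of each group (replicate 1) and the second with 1 array of each group except siControl with TNF (replicate 2). Array medians lay between 5.26 and 5.32 on the log2 scale over all clusters, and any 2 arrays correlated at 0.993 or more. The comparisons ask what the siRNA against p53 changes in these cells with and without the cytokine, and how the cytokine response compares between both kinds of cells.

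Without TNF, few single transcripts separated sip53 from siControl cells (2 arrays each). C1D, which encodes a nuclear cofactor of the RNA exosome, fell by 0.94 (SE 0.0422, adjusted p = 0.0273 with limma, and 0.272 with the run as a block), and the unnamed clusters 7951701 and 8151709 differed by -1.0 (SE 0.044) and 0.88 (SE 0.0396), each with an adjusted p of 0.0273 (0.272 with the block). Cluster 7951701 had a mean level of 4.79 over all arrays, below the median of every array, and no detection limit could be set. C1D is represented by 4 clusters with differences between -0.72 and -1.94 in single pairs of arrays. Copies of this gene share sequence, so their levels are uncertain. GK (glycerol kinase) was 0.60 higher (SE 0.0469, adjusted p = 0.113) and PIK3R1, the regulatory subunit of PI3-kinase, 0.54 higher (SE 0.0441, adjusted p = 0.114), and neither passed. ZNF43 (0.50), SCUBE3 (0.52) and VPS50 (0.52) were the other genes nearest to the threshold on the higher side, and PLAAT1 (-0.52), COMMD6 (-0.50) and SLC35E3 (-0.44) on the lower side, each with an adjusted p of 0.113 or 0.114. Among genes regulated by wild-type p53, CDKN1A, the inhibitor of cyclin-dependent kinases, differed by -0.16 (SE 0.283) and MDM2, the ubiquitin ligase of p53, by 0.19 (SE 0.0393), with adjusted p = 0.842 and 0.198. NFKBIA (0.15), TNFAIP3 (0.29), CXCL8 (-0.38), IL6 (-0.02), ICAM1 (-0.04) and MMP9 (0.09) did not pass either (adjusted p from 0.259 to 0.966).

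In total 4 of 28869 clusters passed, 1 higher and 3 lower, and 4117 (14.3%) had an unadjusted p under 0.05. With the run as a block 0 passed (smallest adjusted p = 0.174), and 1855 clusters (6.43%) had an unadjusted p under 0.05. An analysis of variance without moderation called 95 clusters and an additive model of the siRNA and TNF over all 7 arrays 58, against 0 and 1 with the run term. Leaving out any 1 of 6 arrays also left 0, with an adjusted p for C1D between 0.099 and 0.486. A difference of at least 1.5-fold was seen in 99 clusters, 36 higher and 63 lower. The smallest q in the authors' deposited table is 0.481 without TNF.

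Genes of cholesterol synthesis and interferon-stimulated genes rose in sip53 cells without TNF, while hypoxia genes fell, by camera at its preset correlation and with an adjusted p = 0.515 for each with an estimated correlation. Of 26 cholesterol synthesis genes, 24 were higher (median 0.20, adjusted p = 2.51e-07 with camera, and adjusted p = 0.515 with an estimated correlation). Leading members were FDPS (0.31), ACAT2 (0.28) and NSDHL (0.22), enzymes of the pathway. Of 51 interferon-stimulated genes, 42 were higher (median 0.14, adjusted p = 1.4e-05, and adjusted p = 0.515 with an estimated correlation). The antiviral genes among them included OAS1 at 0.62, IFIT2 at 0.52 and MX1 at 0.50. The list for MHC class I antigen presentation shifted up (median 0.08, 18 of 22 higher, adjusted p = 0.00955, and adjusted p = 0.829 with an estimated correlation). The immunoproteasome genes PSMB8 and PSMB9 were at 0.36 and 0.34 and the proteasome activator PSME2 at 0.50. Of 32 hypoxia and glycolysis genes, 25 were lower (median -0.12, adjusted p = 4.36e-04, and adjusted p = 0.515 with an estimated correlation). These included PDK1 (-0.38), VEGFA (-0.32) and BNIP3 (-0.26). No member of these lists passed over all genes. Adjusted over the list alone, 5 cholesterol, 4 interferon and 5 MHC class I genes were higher and 3 hypoxia genes lower. The 44 targets of wild-type p53 had a median of 0.07 (28 higher, adjusted p = 0.069). The other 15 lists were not called, among them mesenchymal genes (median 0.01, adjusted p = 0.894) and markers of leukocytes (-0.02, adjusted p = 0.52), stromal and endothelial cells (0.00, adjusted p = 0.894) and pancreatic acinar and endocrine cells (-0.02, adjusted p = 0.655). Without sip53 replicate 2 the MHC class I list lost its call (median 0.04, adjusted p = 0.197) and the interferon median was 0.07 (adjusted p = 0.00295), and fry called 0 of the 20 lists (smallest adjusted p = 0.111).

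With TNF, NF-kB targets rose and proliferation genes fell as lists in siControl cells, read from 1 array with TNF against 2 without. These calls, made with camera at its preset correlation, were lost at an adjusted p = 0.532 for NF-kB targets and adjusted p = 0.546 for proliferation genes with an estimated correlation. TNFAIP3, an enzyme that restrains NF-kB, was 1.45 higher (SE 0.354, adjusted p = 0.183), and NFKBIA, the NF-kB inhibitor, 1.03 higher (SE 0.343, adjusted p = 0.246). The chemokines CCL5 and CXCL8 were 1.48 (SE 0.17, adjusted p = 0.128) and 1.04 higher (SE 0.134, adjusted p = 0.129). CTSS, which encodes the protease cathepsin S, had the largest moderated statistic among higher genes (2.25, SE 0.16, adjusted p = 0.11), and MMP2, a gelatinase, among lower genes (-1.01, SE 0.0611, adjusted p = 0.11). EGR1, an immediate early transcription factor, differed by -1.99 (SE 0.596) and CDH1, the epithelial cadherin, by -1.86 (SE 0.442), with adjusted p = 0.218 and 0.181. THNSL2 (0.76), SCUBE3 (0.74), SNX29P2 (0.67) and MAP7 (0.64) stood next to CTSS, and NUPR1 (-0.81), ATP8B1 (-0.77), PEAR1 (-0.67) and OARD1 (-0.57) next to MMP2. ICAM1 (0.81), CDKN1A (0.92), MMP9 (0.28), IL6 (0.18) and MDM2 (-0.07) had adjusted p from 0.213 to 0.475.

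By limma 0 of 28869 clusters passed for TNF in siControl cells (smallest adjusted p = 0.11, and 0.645 with the run as a block), and 4910 (17.0%) had an unadjusted p under 0.05 against 2010 (6.96%) with the block. An analysis of variance without moderation called 93 clusters and the additive model 6; with the run term each called 0. A difference of at least 1.5-fold was seen in 536 clusters, 286 higher and 250 lower.

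As groups, 12 of the 20 lists shifted with TNF in siControl cells, 7 up and 5 down, at the preset correlation (smallest adjusted p = 0.532 with an estimated correlation). Each of these calls was kept whichever array of another group was left out, but that leaves the fold changes as they are and alters only the spread. The lone siControl array with TNF cannot be left out. NF-kB target genes rose (median 0.27, 50 of 60 higher, adjusted p = 8.33e-08, and adjusted p = 0.532 with an estimated correlation). Adjusted over the list alone, 7 were higher and 1 lower. MHC class I genes rose (median 0.37, 18 of 22 higher, adjusted p = 2.99e-08, and adjusted p = 0.532 with an estimated correlation). Adjusted over the list alone, 15 were higher, such as TAPBPL (0.79), TAP2 (0.41) and HLA-G (0.35), which serve peptide loading and presentation. Feedback inhibitors of NF-kB shifted up (median 0.32, adjusted p = 0.00523, and adjusted p = 0.546 with an estimated correlation), with TNIP1 at 0.98 and TNIP2 at 0.47 beside TNFAIP3. Cytokines and chemokines (median 0.12, adjusted p = 0.00476), extracellular proteases (0.10, adjusted p = 0.00493) and TNF receptor signalling genes (0.10, adjusted p = 0.0176) shifted up too, each with an adjusted p = 0.532 with an estimated correlation. The protease MMP7 was 0.95 higher and MLKL, the executor of necroptosis, 0.87 higher. The interferon-stimulated list shifted up (median 0.12, adjusted p = 0.0184, and adjusted p = 0.546 with an estimated correlation), with MX1 at 0.63 but HERC5 at -0.55 and IFIT2 at -0.42.

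Genes of the cell cycle and of the stress response to unfolded protein and amino acid shortage fell with TNF in siControl cells at the preset correlation. Of 45 mitosis genes 44 were lower (median -0.46, adjusted p = 1.14e-08) and of 44 DNA replication genes 42 (median -0.35, adjusted p = 1.93e-06), each with an adjusted p = 0.546 with an estimated correlation. TOP2A, a topoisomerase of dividing cells, differed by -0.71 and PRC1, a spindle protein, by -0.56. Of 35 stress response genes 32 were lower (median -0.32, adjusted p = 1.14e-08, and adjusted p = 0.532 with an estimated correlation). Adjusted over the list alone, 9 were lower and 1 higher, with PHGDH, the first enzyme of serine synthesis, at -0.59 and CTH at -0.46. Ribosomal protein genes (median -0.11, 36 of 42 lower, adjusted p = 1.95e-04, and adjusted p = 0.532 with an estimated correlation) and epithelial junction genes (median -0.13, 24 of 32 lower, adjusted p = 0.006, and adjusted p = 0.539 with an estimated correlation) fell as lists. The immediate early list (median -0.08, adjusted p = 0.0572) and cholesterol synthesis (0.09, adjusted p = 0.521) were not called. With fry 0 lists passed (smallest adjusted p = 0.0527). Without siControl replicate 1 the medians were -0.08 for epithelial junction genes (adjusted p = 0.0499) and 0.06 for TNF receptor signalling genes (adjusted p = 0.032).

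**Figure D1:**
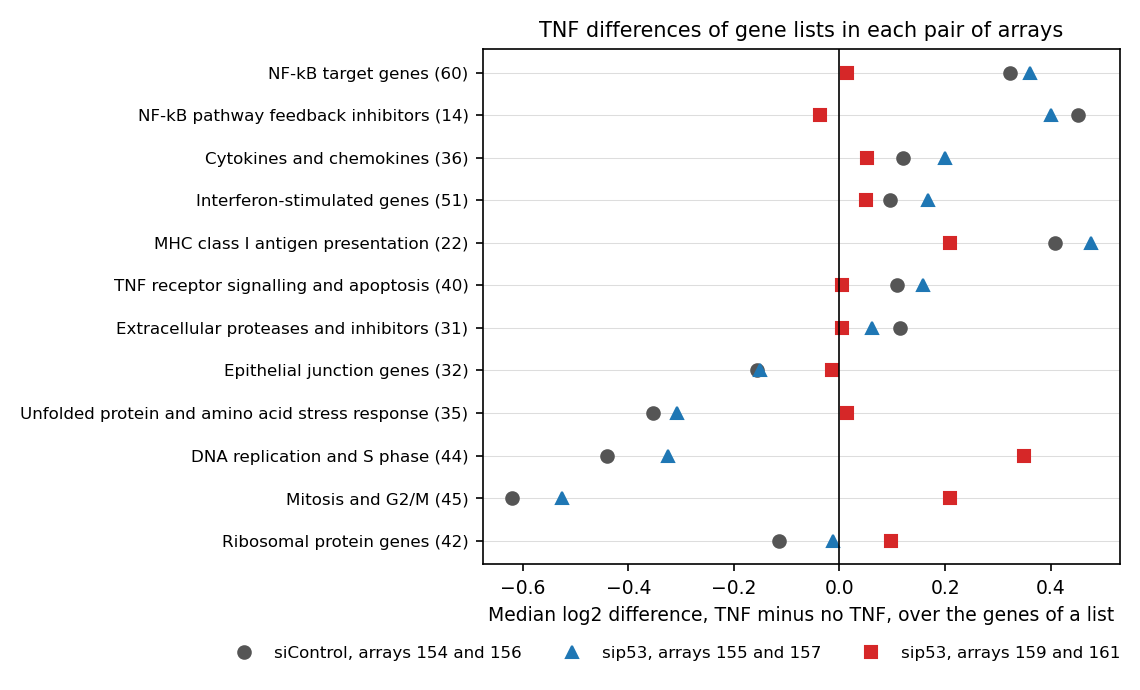
Median log2 difference (TNF minus no TNF, x axis) over the genes of 12 lists (y axis, number of genes in brackets) in each pair of arrays from the same run: circles, siControl; triangles, sip53 in run 1; squares, sip53 in run 2. The first 2 pairs lie close together, at 0.323 and 0.361 for NF-kB target genes, while the sip53 arrays of run 2 differ by 0.0143 there and by 0.349 for DNA replication genes.

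In sip53 cells (2 arrays with TNF against 2 without), MHC class I genes and cytokines rose with TNF as lists (camera at its preset correlation, and adjusted p = 0.586 with an estimated correlation). The medians in run 1 and run 2 were 0.476 and 0.209 for MHC class I genes. For cytokines they were 0.199 (27 of 36 higher) and 0.0522 (21 of 36 higher). Some single genes differed widely between both pairs of arrays. CCL5 was 1.42 higher (SE 0.139, adjusted p = 0.161), CTSS 1.07 higher (SE 0.131, adjusted p = 0.169) and CXCL8 0.70 higher (SE 0.11, adjusted p = 0.172). FASN, the fatty acid synthase, differed by -0.56 (SE 0.0404, adjusted p = 0.161) and MMP2 by -0.57 (SE 0.0499, adjusted p = 0.161). NFKBIA was 1.05 higher in the pair of run 1 and 0.00 higher in that of run 2; TNFAIP3 was 1.09 and 0.04 higher, ICAM1 1.07 and 0.11 higher. CDKN1A differed by 1.07 and -0.07 in these pairs. Over both pairs NFKBIA (0.53), TNFAIP3 (0.56), ICAM1 (0.59), CDKN1A (0.50), IL6 (0.08), MMP9 (0.13) and MDM2 (-0.10) had adjusted p from 0.388 to 0.678. SCUBE3 (0.61), PYCARD (0.44), the inflammasome adaptor, MGC87042 (0.57) and PRSS3P2 (0.56) stood next to CCL5 among higher genes, and LOC100130876 (-0.91), CYP4F30P (-0.65), POTEF (-0.55) and POTEE (-0.53) next to FASN among lower genes.

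By limma 0 clusters passed for TNF in sip53 cells (smallest adjusted p = 0.161, and 0.803 with the run as a block), with 3736 (12.9%) at an unadjusted p under 0.05 and 1707 (5.91%) with the block. An analysis of variance without moderation called 86 clusters and the additive model 6; with the run term each called 0. A difference of at least 1.5-fold was seen in 104 clusters, 59 higher and 45 lower.

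MHC class I genes rose with TNF in sip53 cells too (median 0.35, 19 of 22 higher, adjusted p = 5.47e-11, and adjusted p = 0.586 with an estimated correlation). Adjusted over the list alone 15 were higher, and 19 and 21 of the 22 were higher in the separate pairs. NF-kB target genes rose (median 0.21, 48 of 60 higher, adjusted p = 8.41e-06, and adjusted p = 0.611 with an estimated correlation), with medians of 0.361 in run 1 and 0.0143 in run 2. Cytokines and chemokines (median 0.12, adjusted p = 6.19e-05) and interferon-stimulated genes (0.14, adjusted p = 1.07e-04) rose, each with an adjusted p = 0.586 with an estimated correlation. IL32, a cytokine induced by TNF, was 0.67 higher and TRIM21, an antibody receptor, 0.61 higher. TNF receptor signalling genes (median 0.08, adjusted p = 0.00236) and hypoxia genes (0.09, adjusted p = 0.0109, with BNIP3 at 0.23) shifted up, each with an adjusted p = 0.586 with an estimated correlation. Feedback inhibitors of NF-kB (median 0.22, adjusted p = 0.0131) and ribosomal protein genes (0.04, adjusted p = 0.0236) shifted up, and epithelial junction genes (-0.10, adjusted p = 0.0379) and stress response genes (-0.16, adjusted p = 0.00382) shifted down, each with an adjusted p = 0.611 with an estimated correlation. Mitosis genes shifted down (median -0.16, 39 of 45 lower, adjusted p = 0.0131, and adjusted p = 0.802 with an estimated correlation), from medians of -0.526 in run 1 and 0.210 in run 2. DNA replication genes had a median of -0.01 (adjusted p = 0.724), from -0.325 (4 of 44 higher) and 0.349 (44 of 44 higher). Proteases were not called (0.03, adjusted p = 0.209), and fry passed 0 lists (smallest adjusted p = 0.153).

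Of these 11 calls, those for NF-kB target genes, cytokines, interferon-stimulated genes and MHC class I genes were kept with each of 6 arrays left out, and the other 7 were not. Without sip53 with TNF replicate 1 the NF-kB median was 0.06 (adjusted p = 0.0166), and without sip53 replicate 1 the interferon median was 0.09 (adjusted p = 0.0115). Without sip53 with TNF replicate 1, 6 of the 11 lists lost their call or turned. Calls for feedback inhibitors (adjusted p = 0.557), epithelial junctions (0.461), TNF receptor signalling (0.142), stress response (0.618) and hypoxia (0.104) were lost. Mitosis turned to a median of 0.10 (adjusted p = 0.0277). Without sip53 replicate 1 the calls for feedback inhibitors (0.137), mitosis (0.613), epithelial junctions (0.108) and stress response (0.0747) were lost. The ribosomal call was lost without sip53 replicate 2 (0.239), without sip53 with TNF replicate 2 (0.603), or after quantile normalization (0.0884). Without sip53 with TNF replicate 2, DNA replication genes had a median of -0.23 (adjusted p = 2.31e-06).

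**Figure D2:**
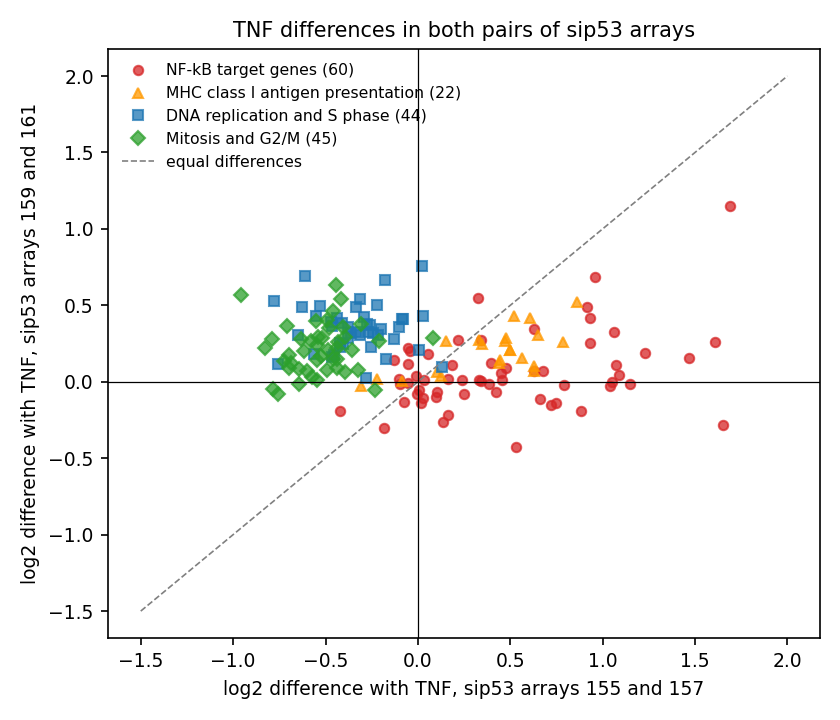
Log2 difference with TNF in sip53 cells for each gene of 4 lists (numbers of genes in brackets), in the pair of run 1 (x axis) and that of run 2 (y axis); the dashed line marks equal differences. Most NF-kB target genes spread along the x axis near 0 on the y axis (median 0.0143), and DNA replication and mitosis genes lie left of 0 and mostly above it (medians 0.349 and 0.210 on the y axis).

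With TNF present, interferon-stimulated and DNA replication genes were higher as lists in sip53 cells (2 arrays) than in siControl cells (1 array), by camera at its preset correlation and with an adjusted p = 0.719 for both with an estimated correlation. No single cluster passed. IFIT2 was 0.84 higher (SE 0.0575), PEAR1 0.86 (SE 0.0659), MMP2 0.77 (SE 0.0611), PPP1R14A, an inhibitor of myosin phosphatase, 0.68 (SE 0.0549) and PYCARD 0.64 higher (SE 0.0543), each with an adjusted p of 0.0728. MMP1, the interstitial collagenase, differed by -1.67 (SE 0.237, adjusted p = 0.094), CTSS by -1.21 (SE 0.16, adjusted p = 0.094), LOX, which cross-links collagen, by -0.97 (SE 0.106, adjusted p = 0.0827) and CXCL8 by -0.72 (SE 0.134, adjusted p = 0.118). C1D differed by -0.74 (SE 0.0517), RABL2A by -0.73, RBMS2 by -0.70 and SPATA13 by -0.70, each with an adjusted p of 0.0728. CDKN1A (-0.57), TNFAIP3 (-0.60), NFKBIA (-0.36), ICAM1 (-0.26), IL6 (-0.11), MMP9 (-0.06) and MDM2 (0.17) had adjusted p from 0.184 to 0.738.

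By limma 0 clusters passed for the knockdown with TNF (smallest adjusted p = 0.0589, and 0.361 with the run as a block), with 5453 (18.9%) at an unadjusted p under 0.05 and 2311 (8.01%) with the block. An analysis of variance without moderation called 192 clusters and the additive model 58; with the run term these called 0 and 1. A difference of at least 1.5-fold was seen in 487 clusters, 255 higher and 232 lower. The smallest q in the authors' deposited table is 0.234 for this comparison.

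Of 9 lists called for the knockdown with TNF, all up, DNA replication genes had the largest median over both sip53 arrays (0.40, 43 of 44 higher, adjusted p = 1.73e-08, and adjusted p = 0.719 with an estimated correlation). The epigenetic regulator UHRF1 was at 0.73 and the replication factor GINS4 at 0.66, and 1 member was higher adjusted over the list alone. Interferon-stimulated genes (median 0.14, 37 of 51 higher) and ribosomal protein genes (0.08, 30 of 42 higher) rose with an adjusted p of 2.60e-04 each, and adjusted p = 0.719 with an estimated correlation. Of the interferon genes 4 were higher adjusted over the list alone, among them OAS1 (0.60) and HERC5 (0.52). Targets of wild-type p53 rose (median 0.09, 32 of 44 higher, adjusted p = 0.012, and adjusted p = 0.719 with an estimated correlation), with the phosphatase PPM1D at 0.52 and TP53I11 at 0.36. Cholesterol synthesis (median 0.07, adjusted p = 0.0239, with ACAT2 at 0.47), epithelial junction genes (0.11, adjusted p = 0.0396, with JUP at 0.54 and KRT18 at 0.41) and immediate early genes (0.09, adjusted p = 0.0349, with DUSP6 at 0.52) shifted up, each with an adjusted p = 0.719 with an estimated correlation. Mitosis genes (median 0.30, 39 of 45 higher, adjusted p = 2.60e-04, and adjusted p = 0.832 with an estimated correlation) and stress response genes (0.18, 28 of 35 higher, adjusted p = 0.00376, and adjusted p = 0.814 with an estimated correlation) shifted up. NF-kB target genes had a median of -0.09 (43 of 60 lower, adjusted p = 0.0848, and 0.0329 with the run as a block; adjusted p = 0.832 and 0.875 with an estimated correlation). Fry passed 2 lists, p53 targets (adjusted p = 0.0404) and, lower, leukocyte markers (median -0.05, adjusted p = 0.0282), of which CD68 differed by -0.53.

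Without sip53 with TNF replicate 2 the calls for mitosis (median 0.03, adjusted p = 0.413), stress response (0.08, adjusted p = 0.204) and epithelial junction genes (0.02, adjusted p = 0.371) were lost, and the NF-kB median was 0.01. The DNA replication median was then 0.18 (adjusted p = 5.94e-05), below the interferon median of 0.19, against 0.64 without sip53 with TNF replicate 1. Without sip53 with TNF replicate 1 the interferon median was 0.05 (adjusted p = 0.0134), and cholesterol synthesis (adjusted p = 0.286) and immediate early genes (0.0545) were lost. Both also missed after quantile normalization (0.135 and 0.101), as did epithelial junction genes (0.0903).

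The TNF responses of sip53 and siControl cells differed for gene lists by camera at its preset correlation (adjusted p = 0.86 to 0.887 with an estimated correlation), and no single cluster passed. DNA replication genes responded 0.30 more positively in sip53 cells (median, 42 of 44, adjusted p = 1.97e-05), as did mitosis genes by 0.31 (44 of 45, adjusted p = 7.18e-04) and stress response genes by 0.20 (26 of 35, adjusted p = 7.48e-04), each with an adjusted p = 0.887 with an estimated correlation. Ribosomal protein genes (median 0.14, 36 of 42 higher, adjusted p = 1.87e-05), hypoxia genes (0.08, 21 of 32 higher, adjusted p = 0.00618) and immediate early genes (0.12, 21 of 27 higher, adjusted p = 0.00618) differed the same way, each with an adjusted p = 0.86 with an estimated correlation. GINS4 (0.62), NUSAP1 (0.53), PHGDH (0.54), RPL22 (0.60), PGAM1 (0.34) and DUSP6 (0.52) were among the members with the smallest p, and 1 immediate early gene passed adjusted over the list alone. Fry passed 0 lists (smallest adjusted p = 0.269). Without sip53 with TNF replicate 2 the median fell to 0.03 for mitosis (adjusted p = 0.526) and 0.11 for stress response genes (adjusted p = 0.0736), and both calls were lost. DNA replication (0.11, adjusted p = 0.0264), hypoxia (0.11, adjusted p = 0.00167), immediate early (0.12, adjusted p = 0.00311) and ribosomal genes (0.10, adjusted p = 0.00167) kept theirs.

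Single genes in this comparison included CTSS (-1.18, SE 0.206), MMP7 (-0.53, SE 0.104) and the acute phase gene SAA1 (-0.41, SE 0.0643), each with a smaller response in sip53 cells and an adjusted p of 0.27. AOC3 (-1.23), UNQ6167 (-0.82), SNORA23 (-0.75), HEXA-AS1 (-0.69) and ATP7B (-0.66) had the largest moderated statistics on the lower side, and TINCR (0.74), HSP90AB3P (0.67), OARD1 (0.66), HPCA (0.62) and SLC2A12 (0.52) on the higher side, with the same adjusted p. TNFAIP3 (-0.89, SE 0.457), NFKBIA (-0.51, SE 0.443), CDKN1A (-0.41), CXCL8 (-0.34), ICAM1 (-0.22), MMP9 (-0.15), IL6 (-0.10) and MDM2 (-0.03) had adjusted p from 0.476 to 0.89. SAA1 (group means from 3.99 to 4.48), IL6 (4.03 to 4.23) and MMP9 (4.05 to 4.33) lay below the median of every array. No detection limit could be set, so differences of these genes may be noise. By limma 0 clusters passed (smallest adjusted p = 0.27, and 0.983 with the run as a block), with 3678 (12.7%) at an unadjusted p under 0.05 and 1293 (4.48%) with the block. An analysis of variance without moderation called 67, and 0 with the run term. NF-kB target genes responded less in sip53 cells (median -0.14, 44 of 60 lower), short of the threshold (adjusted p = 0.0627, and 0.0239 with the run as a block; adjusted p = 0.887 and 0.872 with an estimated correlation), and without sip53 with TNF replicate 2 the median was -0.01 (adjusted p = 0.919). Without sip53 replicate 2 the medians were 0.20 for DNA replication, 0.18 for mitosis and 0.05 for hypoxia genes. The mitosis call was also lost without siControl replicate 1 (adjusted p = 0.0762), and that for hypoxia without siControl replicate 2 (0.0967), without sip53 with TNF replicate 1 (0.0614) or after quantile normalization (0.0609).

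Across the 28869 clusters, which are not independent replicates, the TNF fold changes of siControl and sip53 cells correlated at r = 0.291 (rho = 0.169), and the knockdown fold changes without and with TNF at r = 0.289 (rho = 0.229). The comparisons within each of these correlations share no array. Among the arrays of run 1 alone, the TNF responses correlated at r = 0.508 (rho = 0.355). The siControl response of run 1 and the sip53 response of run 2 correlated at r = -0.129 (rho = -0.129). Knockdown differences without TNF correlated at r = 0.160 (rho = 0.133) between the runs, and TNF differences in sip53 cells at r = 0.0874 (rho = 0.0661).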

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

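The tests of explanations in this part were all chosen after the results were seen, while the comparison of the TNF responses list by list was planned.

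In 6 gene lists the TNF response of sip53 cells differed from that of siControl cells by a direct test of the difference (camera at its preset correlation, and adjusted p = 0.86 to 0.887 with an estimated correlation). The median log2 differences were 0.303 for DNA replication, 0.309 for mitosis, 0.200 for the stress response, 0.0765 for hypoxia, 0.119 for immediate early and 0.137 for ribosomal protein genes. For mitosis genes, sip53 with TNF replicate 2 alone is a candidate explanation, since without it the median was 0.0274 (adjusted p = 0.526), while for stress response genes this stays open, at a median of 0.112 without it (adjusted p = 0.0736) and 0.0894 (23 of 35 higher) in run 1 alone. At the preset correlation the other 4 lists passed without that array, at an adjusted p of 0.0264 or less (DNA replication at a median of 0.112), so that array is not the whole cause of their calls, which all miss with an estimated correlation; in run 1 alone their medians were 0.109 for DNA replication, 0.121 for ribosomal, 0.0907 for immediate early and 0.0809 for hypoxia genes. An effect of the siRNA against p53 on the response and a peculiarity of the single siControl array with TNF both stay open and were not tested.

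The NF-kB response was nearly missing on sip53 with TNF replicate 2, where feedback inhibitors had a median difference of -0.0377 from sip53 replicate 2, against 0.400 in the other sip53 pair. For cells that received no TNF the test was ambiguous: the 141 clusters at least 1.5-fold higher with TNF in both pairs of run 1 had a median of 0.107 in the sip53 pair of run 2, above 100% of 10000 sets matched on level (central 95% from -0.037 to 0.036), and 11 of them, among them CCL5 (1.15) and CTSS (0.79), were at least 1.5-fold higher against 1 lower (7.8% higher against 0.258% of other clusters), but the 125 clusters at least 1.5-fold lower in both pairs of run 1 rose there as well (median 0.116, above 100%). A uniformly weaker response would leave those 125 clusters lower with TNF, yet between sip53 and siControl arrays of run 2 without TNF they differed by 0.117 (above 100%) with 8 at least 1.5-fold higher and 1 lower, against the 48.8th percentile, 2 and 2 for the 141, so shifts of that size arose without TNF. The random sets were matched on mean level alone and not on how genes vary together, so these percentages are not p-values. TNF signalling that had ended by harvest may leave longer-lived transcripts high, and the MHC class I median lay 0.246 above that of the feedback inhibitors, but transcript lifetimes were not measured. These explanations cannot be told apart from other differences between cultures, and no biological explanation was tested, since both sip53 arrays with TNF belong to the same group.

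The 4 clusters called for the knockdown without TNF were weighed against the run difference removed before deposit, which leaves the spread between arrays too small. With a run term 0 clusters passed: the differences stayed the same, while the SE of C1D (-0.94) went from 0.0422 to 0.0748. That fit has 2 residual degrees of freedom in place of 3 and also re-estimates the spread pooled over clusters, so both enter the SE. In an additive model of all 7 arrays with a run term 1 cluster passed, and C1D had an adjusted p of 0.0943. Of 33 splits of the 7 arrays into 4 and 3 that could be fitted in that model, only the real one called any cluster (1 against 0). A count of 1 over 33 overlapping splits is too little to exclude chance. It also does not cover C1D, which did not pass in that model. For C1D and both unnamed clusters, the call rests on the limma fit that counts 3 residual degrees of freedom where 2 remain. Their adjusted p was 0.0273 in that fit and 0.272 with the run term. An effect of the siRNA is untested, as its sequence is not given in the sources used here.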

How the results depend on the processing

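Among the alternatives given here, the analysis of variance with the run term, the additive model with the run term and the correlations within single runs were chosen after the data had been seen; the others were planned. The cause of a change was not tested unless it is named.

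The count of 4 clusters for the knockdown without TNF became 0 with trended and robust variances, with the array number block, with only the groups compared (which leaves fewer arrays), with each of 6 arrays left out, and in the analysis of variance with the run term; it became 1 in the additive model with the run term, 58 in the additive model, 95 in the analysis of variance without moderation, and 86 at an unadjusted p with a fold minimum of 1.5. Counts of 0 rose for TNF in siControl cells to 93 in the analysis of variance, 6 in the additive model and 429 at an unadjusted p with the fold minimum, for TNF in sip53 cells to 86, 6 and 80, and for the knockdown with TNF to 192, 58 and 396, with 311 at an adjusted p under 0.10 and 1 in the additive model with the run term. For the difference of TNF responses the counts were 67 in the analysis of variance and 343 at an unadjusted p with the fold minimum. Moderation pools spread over clusters, and the run block takes back a degree of freedom that the removal of the run difference had used.

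List counts of 4, 12, 11, 9 and 6 became 0 with an estimated correlation, and 0 with fry except 2 for the knockdown with TNF. With the array number block they were 4, 13, 11, 10 and 7, with each list called without the block kept; the added lists were immediate early genes for TNF in siControl cells and NF-kB target genes in the last pair. Leaving out 1 array turned lists for TNF in sip53 cells: DNA replication ranged from -0.233 to 0.238 and mitosis from -0.417 to 0.0983.

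C1D kept its direction without TNF with each of 6 arrays left out, and missed the threshold there (adjusted p from 0.099 to 0.486). Named genes far from the threshold changed sign when 1 array was left out. Without TNF the knockdown differences ranged from -0.364 to 0.0473 for CDKN1A, -0.304 to 0.221 for ICAM1, -0.0732 to 0.0419 for IL6 and -0.0486 to 0.347 for NFKBIA. With TNF they ranged from -0.630 to 0.112 for ICAM1, -0.125 to 0.00843 for MMP9 and -0.717 to 0.0056 for NFKBIA, and the differences of TNF responses from -0.588 to 0.154 for ICAM1.

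The correlation of TNF fold changes between siControl and sip53 cells ranged from 0.0338 to 0.441 with 1 array left out; it was 0.508 from the arrays of run 1 only and -0.129 for siControl of run 1 against sip53 of run 2. That of the knockdown fold changes ranged from 0.150 to 0.377. Both deposited tables hold the same values, so the planned use of the other table moved nothing. The array number block is the paired analysis of these arrays, by run, and leaves 2 residual degrees of freedom; the labels give no replicate numbers. Over all alternatives, 1055 list results kept their side of the threshold, 111 lost the call, 34 gained it and 2 reversed. Direction was compared only for lists called in the main fit or in the alternative, so lists called in neither may have turned. Among named genes 1799 kept direction and side of the threshold, 7 lost the call and 12 reversed. Signal over background could not be used to limit calls, since no detection limit could be set.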

Other observations

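The genes in this part were chosen after their values were seen, as those at least 1.5-fold apart in the same direction in all 3 pairs of arrays from the same run; the pairs share no array.

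A small set of transcripts differed with TNF in every pair, including the sip53 pair of run 2, where the NF-kB target median was 0.0143. It held 11 clusters that were higher and 2 that were lower, against 6 clusters past 1.5-fold in all pairs with mixed directions. A chance share of 25% in a single direction would hold only for independent pairs, and both run 1 pairs correlated at r = 0.508. Of the clusters higher in both run 1 pairs, 11 were at least 1.5-fold higher in the sip53 pair of run 2 and 1 lower. Of those lower in both run 1 pairs, 2 were lower there and 5 higher, so more of them turned than stayed lower. The chemokines CCL5 (1.40, 1.69 and 1.15 in siControl, then in sip53 of run 1 and run 2) and CXCL1 (1.41, 0.96 and 0.69), the protease gene CTSS (2.24, 1.35 and 0.79) and QPCT, a glutaminyl cyclase that modifies secreted peptides (1.02, 0.91 and 0.77), belonged to the same set. So did TGFB3 (mean 1.91, SD 1.21, n = 3 pairs), S100A3 (1.13, SD 0.455), PLEK2 (0.98, SD 0.328), TMOD1, which caps actin filaments (0.92, SD 0.201), CD74, the invariant chain of MHC class II (0.76, SD 0.102), and an unnamed cluster. LLGL2, a regulator of epithelial polarity, was lower in each pair (-0.69, -0.86 and -0.72), as was the small nucleolar RNA SNORD83B (mean -0.67, SD 0.106).

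Across the 3 knockdown pairs, 1 cluster was higher and 9 lower at 1.5-fold or more, against 2 with mixed directions. Beside the 4 clusters of C1D, PTX3, a secreted pentraxin of innate immunity, was lower in each pair (-0.79 and -0.95 without TNF and -1.03 with TNF), and GK was higher (0.61, 0.59 and 0.66). In the additive model with the run term, GK had an adjusted p of 0.139, and OAS1, PIK3R1 and B3GNT2 an adjusted p of 0.192 with differences of 0.61, 0.57 and -0.62. For the TNF term of that model the smallest adjusted p was 0.178, for CCL5 (1.44, SE 0.109), followed by 0.229 for QPCT (0.86) and SCUBE3 (0.66).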
